A study of Mus musculus with 6 samples.

How the data were processed

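The samples were 6 mRNA sequencing libraries of Tregs from mouse liver, 3 labelled Altre wild type and 3 labelled Altre knockout, all from animals of 14 months. RNA was purified with a micro-scale column kit and libraries were made with a SMARTer kit for low RNA input, per the labels' protocols. The labels do not say whether the 3 libraries of a genotype came from separate animals, so p-values measure the spread between these samples, which may be technical. The libraries of a genotype differed by more than sampling noise (chi-square per gene from 40.5 to 73.2 between pairs), so each was counted as 1 replicate.

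The authors deposited 1 table of 13623 genes with whole-number counts per gene and library, taken here as raw read counts because they are whole numbers with different library totals. The submitters' processing notes name cutadapt, STAR, DESeq2 and the mouse build mm10, without versions, roles or order. The counting tool, the annotation and the use of strand are not given in the sources used here. Per the file headers, the table also holds the authors' mean normalized count (a signal averaged over the 6 libraries), which equals the mean of the counts over 6 size factors within a relative error of 5.3e-15. Per the file headers, it holds the authors' log2 fold change with its standard error, a Wald statistic (a score with no fixed range), a p-value and an adjusted p-value. The deposited log2 fold change is positive where wild type is higher, and a further deposited column, whose header names wild type against knockout, holds its negative and is positive where knockout is higher in all 13623 rows. Values from the authors' deposited table are given here as knockout over wild type. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment of the deposited p-value over the table (largest difference 7.8e-15). The smallest deposited mean normalized count was 5.96, so the table holds only genes above a minimum level, and the totals given are over the genes listed, not the full depth of a library. The deposited statistics were compared with DESeq2 fits to the deposited counts. With the replicate number and genotype as terms the Wald statistics correlated at 0.9996 across genes and 247 genes were called, 244 of them shared with the deposited table. With genotype alone the correlation was 0.931 and 46 genes were called, 45 of them shared.

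In 18 rows the gene name had been turned into a date. These rows, 0.2945% to 0.3078% of the counts of a library, were left out, and 13605 genes were used, of which 99.0% had a name in the mouse gene table used. No row carried the name Altre (0 rows), so the deleted gene was not analysed here and the genotype labels were not checked by it. Text notes beside some genes were not used. Gene positions and sequences came from GENCODE M21 on GRCm38, the same assembly as mm10.

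Total counts per library over the listed genes were 28349682, 25315425 and 27590088 for wild-type replicates 1, 2 and 3 and 25490761, 25617168 and 30870786 for knockout replicates 1, 2 and 3.

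Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test, genotype as the only term), which left 12789 genes, and p-values were adjusted with Benjamini-Hochberg. CPM values use TMM-scaled library sizes. Log2 fold changes are knockout over wild type and each standard error is the fold change divided by the square root of the F statistic. Before the data were examined, 36 gene lists were fixed, covering Treg states, T cell function, metabolism, stress, and markers of other liver and blood cells. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 36 lists. The direction of a list, its median and its mean were compared, and members were also adjusted over the list alone. Library medians of a list are of each member's log2 CPM minus its mean over the 6 libraries.

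The rule for named genes was fixed before the data were examined: up to 12 genes per direction with the largest absolute log2 fold change among genes past an adjusted p of 0.05 whose genotypes do not overlap or, with fewer than 5 such genes, the 10 with the smallest unadjusted p in each direction among genes averaging at least 50 counts. It adds up to 4 members of each list with the smallest p, and Foxp3, Il2ra and Ctla4 always. As no gene passed by edgeR, the unadjusted form applied, and those genes are given without a call; 1 gene that the rule names is not reported here.

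The test was checked on simulated counts of 12398 genes drawn with the real means, dispersions and library sizes for this comparison of 3 against 3 libraries. It called 8.96% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 90.9% of those changed 4-fold, with 7 false calls, and 4.47% of unchanged genes had an unadjusted p under 0.05. A list shifted by 0.5 log2 units was called (adjusted p = 7.97e-18, camera with Benjamini-Hochberg) and 0 other lists were. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called without a difference.

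Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter on low counts and a mean of at least 50 counts, the replicate number as a block, leaving out each library, an adjusted p of 0.1, a fold of at least 2, camera with an estimated correlation, and fry. Added after seeing the data were loess corrections (span 0.3) per library on the GC content of transcripts and on the GC content of the most GC-rich 100 nucleotides of each gene's longest coding transcript, and DESeq2 with the replicate number as a block. Alternatives for normalized values were not needed, since the file holds counts. Random gene sets (10000 per set) were matched on mean log2 CPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.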

Results

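Regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain other immune cells, were taken from the livers of mice at 14 months of age and profiled by mRNA sequencing of low-input libraries. The 6 libraries formed 2 genotypes, 3 from mice with an intact Altre gene (wild type) and 3 from Altre knockout mice, Altre being a long non-coding RNA of Tregs. The counts summed to between 25315425 and 30870786 per library over the 13623 genes listed. The comparison asks which transcripts of liver Tregs in ageing mice differ when Altre is absent. Expression of Altre itself was not analysed here. Gene levels are in CPM, counts scaled to a common library total, and are given as mean ± SD with n = 3 libraries per genotype, and positions are on mouse build GRCm38.

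In knockout Tregs 9 of 36 gene lists shifted, 8 higher and 1 lower, at an adjusted p of 0.05 (camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). None of the 9 was called with a correlation estimated from the data, where the smallest adjusted p was 0.575. The list that fell was that of interferon-induced genes, led by Ifit3b, which averaged 18.5 ± 3.01 CPM in wild type and 5.33 ± 0.483 CPM in knockout. Among those that rose were transcripts typical of naive or resting T cells, such as Ccr7 at 224 ± 44.5 CPM in wild type and 386 ± 81.1 CPM in knockout, and markers of macrophages and Kupffer cells (the resident macrophages of liver), of IL-2 signalling, of cholesterol and fatty acid synthesis and of the cytosolic ribosome. No single gene passed an adjusted p of 0.05 among the 12789 tested with genotype as the only term (edgeR quasi-likelihood test, Benjamini-Hochberg), although 744 genes had an unadjusted p under 0.05. On the same terms DESeq2 called 46 genes and limma-voom 0. With the replicate number added as a block, edgeR called 16 genes and DESeq2 247.

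**Figure D1:**
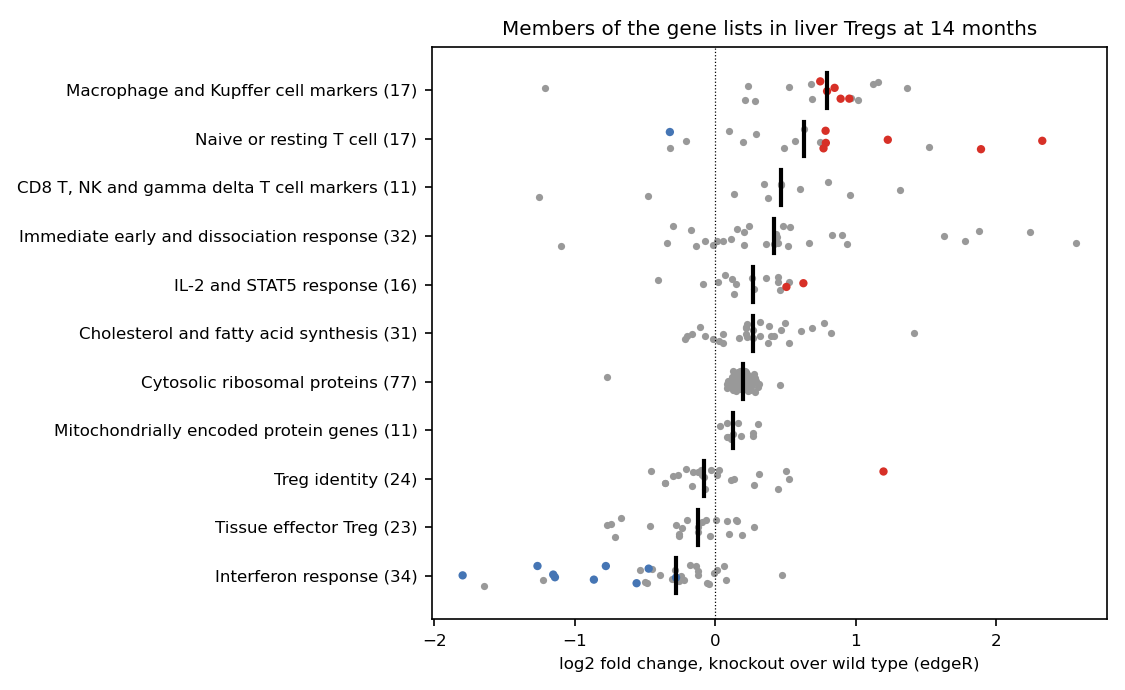
Each point is the log2 fold change (knockout over wild type, edgeR) of 1 measured member of a gene list, black bars are list medians, and numbers in brackets are measured members; red (higher) and blue (lower) points passed an adjusted p of 0.05 over the list alone and grey points did not. The median was 0.80 for macrophage and Kupffer cell markers, 0.63 for naive or resting T cell genes and -0.28 for interferon response genes, and the Treg identity list had members on both sides of 0.

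Of the 34 interferon response genes measured, 30 had a lower mean in knockout and 4 a higher one, with a median log2 fold change of -0.28. Adjusted over the list alone, 9 genes fell and 0 rose, against 0 adjusted over all genes tested. Ifit3b (chromosome 19, 34607970 to 34613401) and Ifit1 (chromosome 19, 34640871 to 34650009), whose products bind viral RNA, had log2 fold changes of -1.80 ± 0.25 and -1.27 ± 0.22 (SE). Ifit1 averaged 106 ± 28.6 CPM in wild type and 43.9 ± 8.56 CPM in knockout. Ifit3b has a near-identical neighbouring copy, Ifit3, so the division of reads between them is uncertain. Ifi27l2a (chromosome 12, 103442167 to 103443680) averaged 678 ± 38.2 CPM in wild type and 460 ± 47.8 CPM in knockout, and Rtp4 (chromosome 16, 23520291 to 23614222) averaged 147 ± 24.7 and 85.4 ± 9.96 CPM. For each of these 4 genes the 3 knockout libraries lay below the 3 wild-type libraries. The list fell as a group with an adjusted p of 6.75e-11 (camera, Benjamini-Hochberg), with adjusted p = 0.575 with an estimated correlation. By fry, which asks whether the genes move one way on balance without comparing them with other genes, the adjusted p was 0.146 and the unadjusted PValue 0.0121. Markers of macrophages and Kupffer cells moved the other way in the same libraries, with medians 0.08, 0.39 and 0.67 log2 units above the mean of all 6 libraries in the knockouts.

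Among the 17 genes of naive or resting T cells, 14 had a higher mean in knockout and 3 a lower one, and the median log2 fold change was 0.63. Adjusted over the list alone, 6 genes rose and 1 fell. Igfbp4 (chromosome 11, 99041244 to 99054392), which encodes a binding protein of insulin-like growth factors, averaged 4.66 ± 2.31 CPM in wild type and 23.4 ± 6.78 CPM in knockout, a log2 fold change of 2.33 ± 0.42 (SE). Ccr7 (chromosome 11, 99144196 to 99155077) encodes a chemokine receptor that guides T cells into lymph nodes, and its log2 fold change was 0.79 ± 0.18 (SE). Satb1, a chromatin organiser of T cells, averaged 31.4 ± 7.76 CPM in wild type and 54.2 ± 14.2 CPM in knockout. The gene that fell was Il7r, the interleukin-7 receptor chain, at 247 ± 13.3 CPM in wild type and 198 ± 10.4 CPM in knockout, named after its values were seen. As a group the list rose with an adjusted p of 2.24e-05 (camera, Benjamini-Hochberg), with adjusted p = 0.590 with an estimated correlation and 0.310 by fry. Macrophage and Kupffer cell markers rose in the same comparison. Their library medians were -0.24, -0.42 and -0.19 log2 units from the mean of all libraries in wild-type replicates 1, 2 and 3. Those of the naive list were -0.18, -0.02 and -0.70, in another order. In knockout replicates 1, 2 and 3 the order was the same, at 0.08, 0.39 and 0.67 for macrophage markers and 0.03, 0.34 and 0.50 for the naive list.

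**Figure D2:**
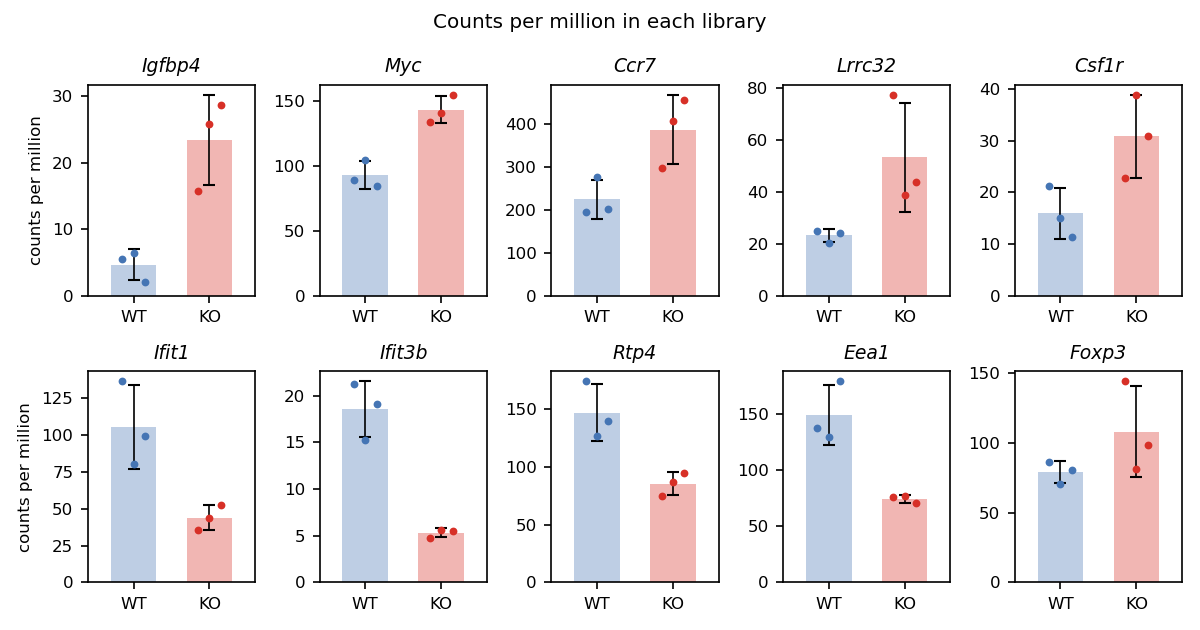
Level in CPM (linear axis from 0) of 10 genes in each library, with 3 wild-type (WT, blue) and 3 knockout (KO, red) points per gene; bars are means and error bars are SD. Igfbp4, Myc, Ccr7, Lrrc32 and Csf1r were higher in all 3 knockout libraries than in any wild-type library, Ifit1, Ifit3b, Rtp4 and Eea1 were lower, and for Foxp3 the genotypes overlapped.

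Foxp3, the transcription factor that defines Tregs, averaged 79.2 ± 7.91 CPM in wild type and 108 ± 32.5 CPM in knockout, a log2 fold change of 0.45 with a 95% interval from -0.0049 to 0.90, and the libraries of the genotypes overlapped. Ctla4, an inhibitory receptor of Tregs, had 264 ± 58.2 and 290 ± 48.6 CPM (log2 fold change 0.13 ± 0.17, SE), a direction that turned in 1 of the alternative settings. Il2ra, the high-affinity chain of the IL-2 receptor, averaged 305 CPM in wild type and 434 CPM in knockout, a log2 fold change of 0.51 ± 0.14 (SE). The 24 Treg identity genes as a group did not pass (adjusted p = 0.891, camera with Benjamini-Hochberg), with 10 higher and 14 lower, a median log2 fold change of -0.08 and a mean of 0.03. Lrrc32 (chromosome 7, 98489283 to 98502181), which docks latent TGF-beta on the Treg surface, was the 1 member that rose when adjusted over the list alone, from 23.3 ± 2.40 to 53.5 ± 21.1 CPM. Of the 16 genes of the IL-2 and STAT5 response, 8 are also in another list, among them Il2ra, Foxp3 and Ctla4 of the Treg identity list. In knockout 14 of the 16 had a higher mean, and the list rose with an adjusted p of 0.00597 (camera, Benjamini-Hochberg), with adjusted p = 0.575 with an estimated correlation and 0.310 by fry. Adjusted over the list alone, 2 of its members rose, Myc and Il2ra, with Myc going from 92.6 ± 10.7 to 143 ± 10.6 CPM. Without wild-type replicate 2 the list's adjusted p was 0.0770, and without knockout replicate 1 it was 0.0837. Its median in knockout replicate 2 (-0.035) lay below that in wild-type replicate 1 (-0.028). Macrophage and Kupffer cell markers, with a median log2 fold change of 0.80, rose in the same comparison. The 2 lists did not move together in every library, as the macrophage median in knockout replicate 2 was 0.39.

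Genes of tissue effector Tregs, such as the transcription factor Nfil3 and the chemokine receptor Cxcr6, had lower means in knockout for 16 of 23 members, and none passed when adjusted over the list alone. Nfil3 averaged 39.6 ± 6.65 CPM in wild type and 23.3 ± 8.73 CPM in knockout, and Cxcr6 67.0 ± 11.9 and 42.1 ± 16.2 CPM. The list had an adjusted p of 0.175 (camera on the edgeR log2 CPM, Benjamini-Hochberg). On DESeq2 variance-stabilised values it was 0.0210, on limma-voom values 0.0301 and without wild-type replicate 2 it was 0.0143, within a range of 0.0143 to 0.971 over all 17 alternatives.

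Macrophage and Kupffer cell markers were higher in knockout for 16 of the 17 measured. The exception, named after its values were seen, was the complement gene C1qc, whose values per library are given further below. Adjusted over the list alone, 5 rose and 0 fell. The authors' deposited table calls 2 members of this list higher in knockout and 1 lower. Csf1r, the receptor for the macrophage growth factor CSF-1, averaged 15.9 ± 4.99 CPM in wild type and 30.8 ± 8.02 CPM in knockout. The complement gene C1qb went from 35.7 ± 5.06 to 59.9 ± 10.9 CPM, the macrophage protein gene Cd5l from 11.2 ± 1.95 to 20.2 ± 3.19 CPM, and the iron exporter gene Slc40a1 from 42.6 ± 7.73 to 79.1 ± 30.6 CPM. The list rose with an adjusted p of 4.65e-07 (camera, Benjamini-Hochberg), with adjusted p = 0.575 with an estimated correlation and 0.146 by fry. No member of this list is held by another list. Markers of CD8 T, NK and gamma delta T cells also rose as a list of 11 genes, 9 of them higher, with a median log2 fold change of 0.47 and an adjusted p of 0.0204 (camera, Benjamini-Hochberg), with adjusted p = 0.590 with an estimated correlation and 0.310 by fry. None of these 11 passed when adjusted over the list alone. Only Tyrobp and Fcer1g were higher with an unadjusted p under 0.05 (edgeR). Tyrobp, which myeloid cells also express, had 10.9 ± 1.73 CPM in wild type and 19.0 ± 5.47 CPM in knockout, and Fcer1g had 17.9 ± 1.43 and 24.8 ± 3.24 CPM. Gzma, a granzyme, had 3.04 ± 1.12 and 1.27 ± 0.807 CPM. Which cells the rise came from was not tested. Leaving out wild-type replicate 1 or 3 or knockout replicate 2 or 3 gave this list an adjusted p of 0.0682, 0.229, 0.199 or 0.0977, and correction for the GC-rich segment of each transcript gave 0.117.

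Genes of cholesterol and fatty acid synthesis had a higher mean in knockout for 25 of 31 members, with a median log2 fold change of 0.27 and an adjusted p of 1.11e-04 (camera, Benjamini-Hochberg), with adjusted p = 0.575 with an estimated correlation and 0.198 by fry. Idi1, Sqle, Msmo1 and Hmgcs1, enzymes of the sterol pathway, had the smallest p-values of the list. Sqle averaged 17.9 ± 5.28 CPM in wild type and 28.7 ± 4.85 CPM in knockout, and Hmgcs1 18.4 ± 1.66 and 25.5 ± 1.69 CPM, and 0 members passed when adjusted over the list alone. Of 77 cytosolic ribosomal protein genes, 76 were higher in knockout by a small amount, the median log2 fold change being 0.19, as for Rpsa at 569 ± 47.9 and 705 ± 54.5 CPM. That list rose with an adjusted p of 7.65e-09 (camera, Benjamini-Hochberg), with adjusted p = 0.758 with an estimated correlation and 0.544 by fry. Its library medians overlapped between genotypes, at -0.23, -0.02 and -0.04 log2 units from the mean of all libraries in wild-type replicates 1, 2 and 3 and -0.14, 0.26 and 0.16 in knockout replicates 1, 2 and 3. The exception, named after its values were seen, was Rps2 at 661 ± 139 CPM in wild type and 388 ± 256 CPM in knockout. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain where reads were shared. All 11 mitochondrially encoded protein genes measured were higher in knockout, with a median log2 fold change of 0.12 and 0 members passing over the list alone. Among them mt-Nd2, a subunit of respiratory complex I, averaged 412 ± 17.1 CPM in wild type and 497 ± 10.2 CPM in knockout. Their list had an adjusted p of 0.0197 (camera, Benjamini-Hochberg), with adjusted p = 0.758 with an estimated correlation and 0.310 by fry. Counts differed widely between members of this list, for a reason not tested, so they are uncertain as transcript levels. With the replicate number as a block the adjusted p of this list by camera was 0.0570. Without wild-type replicate 1 or 2 or knockout replicate 1 or 2 it was 0.0896, 0.109, 0.196 or 0.186. The median of that list in knockout replicate 3 (-0.073) lay below that in wild-type replicate 3 (-0.069). The 76 nuclear subunits of the respiratory chain had a median log2 fold change of -0.02 and an adjusted p of 0.702 (camera, Benjamini-Hochberg), which became 0.00576 without wild-type replicate 1 and 0.00162 without knockout replicate 2. Macrophage and Kupffer cell markers were higher in the same comparison (16 of 17).

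Immediate early and dissociation response genes, which cells induce within minutes of stimulation or tissue handling, had a higher mean in knockout for 25 of 32 members, with a median log2 fold change of 0.42. The list rose with an adjusted p of 0.0125 (camera, Benjamini-Hochberg), with adjusted p = 0.758 with an estimated correlation and 0.731 by fry. No member passed when adjusted over the list alone. The heat shock genes Dnajb1 and Hspa1b had log2 fold changes of 0.42 ± 0.15 and 2.24 ± 0.90 (SE), while Ier2 had -1.10 ± 0.32 (SE). Hspa1b shares reads with its near-identical copy Hspa1a and is uncertain. Leaving out wild-type replicate 1, wild-type replicate 2 or knockout replicate 3 gave the list an adjusted p of 0.0896, 0.190 or 0.450. Its library medians overlapped between genotypes, at -0.27, -0.36 and 0.22 in wild-type replicates 1, 2 and 3 and 0.02, -0.08 and 0.54 in knockout replicates 1, 2 and 3. In each replicate number, however, the knockout median lay above the wild-type median. With the replicate number as a block the list's adjusted p was 2.58e-05 (camera, Benjamini-Hochberg). The authors' deposited table calls 10 members of this list higher in knockout and 1 lower. Macrophage and Kupffer cell markers were higher in knockout here too, 16 of 17 of them.

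Outside the lists, the genes with the smallest unadjusted p-values that were higher in knockout included Myo6, an actin motor, at 2.47 ± 1.40 CPM in wild type and 13.0 ± 3.61 CPM in knockout, Tgm2, a transglutaminase, at 2.44 ± 0.963 and 8.69 ± 2.11 CPM, Cfp, the complement regulator properdin, at 23.7 ± 5.84 and 46.0 ± 5.78 CPM, Prrg1 at 2.89 ± 0.280 and 9.14 ± 2.10 CPM, and Sema4a, a semaphorin, at 6.05 ± 1.34 and 14.2 ± 3.38 CPM. Those lower in knockout included Eea1 (chromosome 10, 95940650 to 96045518), a tether of early endosomes, at 149 ± 26.7 CPM in wild type and 74.6 ± 3.47 CPM in knockout, Trim59 at 141 ± 20.7 and 83.6 ± 9.63 CPM, Rest, a transcriptional repressor, at 90.1 ± 10.7 and 57.6 ± 5.50 CPM, Ubxn2a at 34.8 ± 8.59 and 17.2 ± 3.30 CPM, and Sumf1, the enzyme that activates sulfatases, with a log2 fold change of -2.20 ± 0.50 (SE). The antisense gene Gm16157 was also among them at 6.14 ± 1.74 and 1.47 ± 0.0644 CPM, and its reads cannot be told from those of the opposite strand if counting ignored strand. Their adjusted p-values, like those of all genes tested, were 0.363 or more (edgeR quasi-likelihood test, Benjamini-Hochberg). The authors' deposited table also calls Eea1, Trim59, Rest, Ubxn2a and Sumf1 lower, with a GC-rich segment of 81%, 86%, 82%, 84% and 81% GC. In the higher genes named here it ran from 70% (Cfp) to 80% (Myo6). A loss of transcripts with such a segment is weighed further below. Sumf1 had 55.8, 24.6 and 13.4 CPM in wild-type replicates 1, 2 and 3 and 9.86, 4.15 and 6.44 CPM in knockout. Trim59, Rest, Ubxn2a and Sumf1 were highest in wild-type replicate 1 and Eea1 in replicate 3. Of the 744 genes with an unadjusted p under 0.05, 396 were lower in knockout and the others higher, where 639 would be found with no difference. In 1313 genes (10.3%) the 3 libraries of one genotype all lay above the 3 of the other, close to the 10% that chance gives. DESeq2 with Benjamini-Hochberg adjustment called 17 genes higher and 29 lower, of which 12 averaged under 50 counts and 7 had no count in one genotype.

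The other 27 lists did not pass, with adjusted p-values from 0.138 to 0.979 (camera, Benjamini-Hochberg). Without knockout replicate 3 the hepatocyte markers, of which 2 were measured, had 0.0256, and without knockout replicate 2 the mitochondrial ribosome had 0.0449, against 0.138 and 0.861 with all libraries. Among these were glycolysis (adjusted p = 0.177), the citric acid cycle (0.156), fatty acid uptake and oxidation (0.891), the cell cycle (0.861), effector T cell cytokines and cytotoxicity (0.240), T cell exhaustion and checkpoint genes (0.521), oxidative stress defence (0.591), endoplasmic reticulum stress (0.670), p53 and senescence genes (0.240) and B cell and plasma cell markers (0.520). In 10 of the 36 lists, none of them called, the median, the mean and the test did not share one sign. They were Treg identity, mitochondrial maintenance and dynamics, fatty acid uptake and oxidation, pro-apoptotic, anti-apoptotic, autophagy and lysosome, chemokine receptors and migration, neutrophil and monocyte markers, dendritic cell markers and the sex-linked check genes.

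The authors' deposited table holds their own DESeq2 test of the same libraries and lists 247 genes with an adjusted p under 0.05, 60 of them higher in knockout and 187 lower. A DESeq2 fit with the replicate number and genotype as terms also called 247 genes, whereas 46 were called with genotype alone. In the authors' deposited table the higher genes with the smallest p-values, named for that reason, were the immediate early genes Jun (2.84 times the wild-type level), Dusp1 (log2 fold change 0.88), Junb (0.88) and Zfp36 (0.65). Igfbp4 (log2 fold change 2.40), Ccr7 (0.78), Myo6 (2.51) and Lrrc32 (1.13) were also among the higher genes of the authors' deposited table. The lower genes with the smallest p-values in the authors' deposited table were Micu2 (log2 fold change -1.47), a regulator of mitochondrial calcium uptake, the kinase gene Prkch (-1.22), the phosphatase gene Ppp4c (-1.33), the translation initiation factor gene Eif3f (-1.33) and the linker histone gene H1f0 (-1.63). Of the genes that the authors' deposited table calls, 58 higher and 186 lower ones could be tested here, and 42 and 152 of them had an unadjusted p under 0.05 by edgeR. Genes of the lower set varied between libraries of 1 genotype as well: over 177 of them, with the interferon list left out, the library medians lay 0.99, 0.51 and -0.0011 log2 units from the mean of all libraries in wild-type replicates 1, 2 and 3, and 0.14, -0.80 and -0.86 in knockout replicates 1, 2 and 3. Prkch, for example, had 756, 451 and 248 CPM in the wild-type libraries and 373, 137 and 131 CPM in the knockout libraries.

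**Figure D3:**
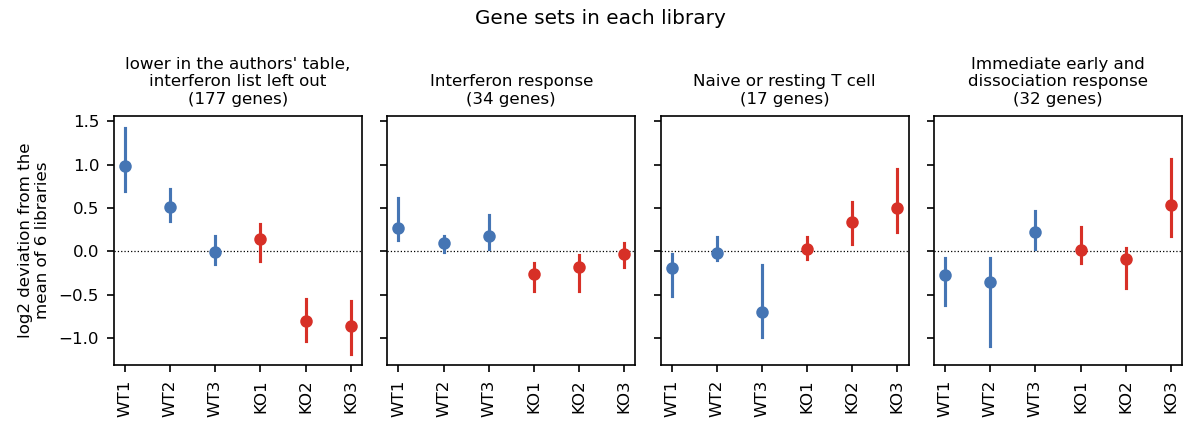
Median (point) and interquartile range (line) of the log2 deviation of 4 gene sets from their mean over the 6 libraries, for wild-type (WT, blue) and knockout (KO, red) replicates. The 177 genes that are lower in the authors' deposited table ranged from 0.99 in wild-type replicate 1 to -0.86 in knockout replicate 3 and overlapped between genotypes, with knockout replicate 1 at 0.14 above wild-type replicate 3; the interferon and naive or resting lists separated the genotypes.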

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

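The GC content correction, the GC-rich segment correction and DESeq2 with the replicate block were chosen only after the results were seen. With no gene called by edgeR, 0 genes were also called by limma-voom, with RLE or upper-quartile factors, without a filter, at a mean of 50 counts, at an adjusted p of 0.1, with a fold of at least 2 and with either GC correction (753 genes at an unadjusted p under 0.05 with GC content and 730 with the GC-rich segment corrected, against 744). DESeq2 called 46 genes, 17 higher and 29 lower. Leaving out a library gave 0 to 1 genes, the 1 gene being lower and found without knockout replicate 1. In the self-test 43.3% of genes changed 2-fold and 90.9% of those changed 4-fold were called.

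The replicate numbers were not taken as pairs, because the labels do not pair the libraries. Same-numbered libraries deviated together with correlations of 0.108, 0.0823 and 0.0239 across genes. All 6 libraries correlated best with their own number, and differently numbered libraries correlated at -0.0858 to 0.00448. The authors' deposited statistics also matched a fit with the replicate number as a term. These values go with a structure shared by same-numbered libraries, but what the numbers mark is not known. The count of genes called depends on this choice, and the absence of calls by edgeR applies to genotype as the only term. With the replicate block edgeR called 16 genes, 5 higher and 11 lower, and DESeq2 with the replicate block called 247, 60 higher and 187 lower. With the replicate block 8 lists were called by camera, and the mitochondrially encoded list had an adjusted p of 0.0570.

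The 9 called lists kept their direction in all 17 alternatives. With an estimated correlation 0 lists were called, with adjusted p-values of 0.575 for interferon response, IL-2 and STAT5, macrophage and Kupffer, and cholesterol and fatty acid synthesis, 0.590 for naive or resting T cells and for CD8 T, NK and gamma delta T cells, and 0.758 for ribosomal proteins, immediate early and mitochondrially encoded genes. By fry 0 lists were called, with 0.146 for interferon response and macrophage and Kupffer, 0.198 for cholesterol and fatty acid synthesis, 0.310 for naive or resting T cells, IL-2 and STAT5, mitochondrially encoded and CD8 T, NK and gamma delta T cells, 0.544 for ribosomal proteins and 0.731 for immediate early genes. The estimated correlations, such as 0.827 among ribosomal proteins and 0.225 among interferon genes, are those that camera uses to widen its null. With the GC-rich segment corrected, the CD8 T, NK and gamma delta T cell list had 0.117; the cause was not tested. Leaving out each library gave ranges of 0.00196 to 0.196 for mitochondrially encoded genes, 6.57e-05 to 0.450 for immediate early genes, 0.00135 to 0.0837 for IL-2 and STAT5 and 0.00253 to 0.229 for CD8 T, NK and gamma delta T cells, with fewer libraries as part of the change. The interferon (2.93e-12 to 4.74e-06), naive (6.24e-07 to 0.00354), macrophage (1.34e-07 to 1.92e-04), cholesterol (1.15e-04 to 0.0175) and ribosomal (6.67e-18 to 0.0250) lists stayed under 0.05 without each library. Of 145 genes named or ranked first in a list, 141 kept their direction in every setting; Ctla4, Nfkbiz and Tnfaip3 turned in 1 setting each and Ly6c2 in 3. The median log2 fold of all genes tested was 0.0039 with TMM and 0.0045 with upper-quartile factors. Pseudocount and low-value alternatives were not run because the file holds counts.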

Other observations

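The tests of the genes lower in the authors' deposited table, the corrections for GC content and for the GC-rich segment, the reading of the planned leave-one-out values as a test of a single library, and the tests on Foxp3 and on the tissue effector list were chosen only after the results were seen. Immediate early genes differed between libraries of 1 genotype, while Jun and Fos were higher in knockout in each replicate number. Jun had 30.3, 15.96 and 107 CPM in wild-type replicates 1, 2 and 3 and 92.7, 36.7 and 345 CPM in knockout replicates 1, 2 and 3, and Fos had 4.28, 9.15 and 59.9 CPM against 28.2, 16.5 and 391 CPM. In both genotypes replicate 3 was the highest for Jun, Fos, Dusp1, Junb, Zfp36 and Rgs2, genes chosen after their values were seen, while Ier2 had 251, 245 and 137 CPM in wild type and 153, 72.4 and 71.4 CPM in knockout. C1qc, the only macrophage marker with a lower mean in knockout, was also chosen after its values were seen. It had 32.8, 22.02 and 6.31 CPM in wild type and 18.2, 3.95 and 4.25 CPM in knockout, whereas C1qb had 34.3, 41.3 and 31.5 CPM against 48.0, 69.2 and 62.6 CPM.

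Transcripts of antibody genes were present in every library, and which cells they came from was not tested. Ighm averaged 3027 ± 576 CPM in wild type and 2788 ± 417 CPM in knockout (SD, n = 3), and Igkc had 407 CPM in knockout replicate 2 against 79.4 to 141 CPM in the other 5 libraries. The antibody variable segment Ighv1-18 had 30.6 CPM in knockout replicate 2 and under 1 CPM in each of the other libraries, and the authors' deposited table calls it higher in knockout with a log2 fold change of 5.40. Among mitochondrially encoded genes, mt-Co1 averaged 4461 ± 92.2 CPM in wild type, while mt-Atp6 averaged 3.88 ± 0.139 and mt-Co3 4.70 ± 0.944 CPM (SD, n = 3). The reason for this gap was not tested, so the counts of these genes may not reflect their transcript levels.

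The first pattern weighed is the lower set of the authors' deposited table. Of its 177 genes outside the interferon list, 151 (85.3%) were highest in wild-type replicate 1 and 114 were higher in knockout replicate 1 than in wild-type replicate 3, so genotype alone did not order the libraries. The most GC-rich 100 nucleotides of these genes had a median GC of 81%, against 73% in random gene sets of matched expression (central 95% of random medians 71% to 74%), and the ratio of replicate 1 to replicate 3 had a median log2 of 0.91 in wild type and 0.91 in knockout, with random medians of -0.0023 and 0.0153. The deposited statistics matched a fit with the replicate number as a term, which favours genes whose same-numbered libraries move in parallel. Similar ratios in both genotypes may thus come partly from how the genes were chosen. From the GC of these segments, a candidate explanation is that transcripts with a GC-rich segment were lost to different degrees in some libraries. In its favour, the deviations of all genes with a value rank-correlated with the GC of this segment at 0.174, -0.0022 and -0.061 in wild-type replicates 1, 2 and 3. In knockout replicates 1, 2 and 3 the correlations were 0.133, -0.205 and -0.081. Yet 2163 other genes with a segment of at least 81% GC had far smaller library medians. They were 0.13, 0.03 and -0.02 in wild-type and 0.05, -0.09 and -0.01 in knockout replicates 1, 2 and 3, not lower in knockout replicate 3 than in wild-type replicate 3. A GC-rich segment alone thus did not bring a shift of this size in those genes. They hold no gene that the authors' deposited table calls, so they cannot exclude such a loss in the set. A part played by the knockout cannot be told apart from such a loss, because the genes of the set were chosen for their difference between genotypes. For the same reason the exact two-sided permutation p of their 6 library medians (0.2, where 0.1 is the smallest possible) decides nothing.

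The second pattern is the fall of the interferon list in knockout. A loss of GC-rich transcripts is argued against, since the list had a median of 65% GC in its most GC-rich 100 nucleotides, below the 72% of random sets, and kept an adjusted p of 9.80e-12 (camera, Benjamini-Hochberg) after the GC-rich segment correction (range over alternatives 4.81e-17 to 0.575). A single library as the source is argued against by the largest adjusted p of 4.74e-06 when each library was left out. A different exposure of the animals may still be the cause and cannot be told apart from the knockout, as 0 label fields tie libraries to a cage, litter or day. Of the 10 splits of the 6 libraries 1, the real one, gave the interferon list so small an unadjusted p (1.88e-12, and 1.81e-08 in the next), but 10 splits are too few for a share under 0.05.

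The third pattern is the rise of naive or resting T cell genes. GC content as the whole cause is argued against by an adjusted p of 3.11e-05 (camera, Benjamini-Hochberg) after its correction (range over alternatives 1.21e-09 to 0.590). An admixture of naive T cells that are not Tregs could raise Ccr7, but would lower Foxp3, whose log2 fold change was 0.45 with a 95% interval from -0.0049 to 0.90, so it stays open. A larger share of resting Tregs in knockout is a hypothesis that also stays open, the tissue effector list having an adjusted p of 0.175 (range over alternatives 0.0143 to 0.971). The grouping of wild-type replicates 1 and 3 with knockout replicate 1 gave the naive list an unadjusted camera p of 2.36e-06, slightly smaller than the 2.49e-06 of the genotypes. The p-value of this list thus does not single out genotype among the groupings.

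With 0 genes called between genotypes and 1 in the highest of the other splits, 10 of 10 splits had to give as many, which says nothing about chance. For lists, the real split called 9 and the highest of the others 8, so that 1 of 10 gave as many; 10 splits are too few for a share under 0.05. The ribosomal list had a smaller unadjusted p in other groupings (2.58e-21 and 7.03e-17) than between genotypes (4.25e-10), which points to a structure of the samples other than genotype.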
